A study of Homo sapiens with 16 samples.

How the data were processed

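Gene expression was measured in HepG2, a human liver tumour cell line, on 1-colour arrays that carry 30968 probes. Total RNA was copied and amplified with aminoallyl-UTP, and the amplified RNA was coupled to the dye Cy5. The 16 samples fall into 4 groups of 4 biological replicates: control without added fatty acid, oleic acid, elaidic acid and stearic acid. Each acid was given at 100 µM for 7 days in serum-free medium. The labels name 2 technical replicates per sample, and the deposited table holds 1 value per probe and sample.

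The deposited values are intensity on a linear scale, with the background subtracted and no scaling between samples. How the authors combined the technical replicates and which background method they used is not stated. Median intensity per sample ran from 20.0 to 76.1, and between 3.31% and 6.24% of the probes of a sample were at or below 0. The number of arrays limits the precision of every value. A gene symbol was given for 17397 probes and none for 13571. Symbols are printed as the table gives them, so that ADFP stands for the gene now called PLIN2, SC4MOL for MSMO1 and SC5DL for SC5D. The table gives no genome build, and no coordinates are printed.

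Values were transformed to log2, and 8029 probes (25.9%) with a value at or below 0 in any sample were left out. Of the probes left out, 84.0% had a mean intensity under 10. The log2 column medians spanned 1.82, so the remaining 22939 probes were quantile normalised between samples. Of these, 13453 had a symbol, for 12085 distinct symbols. Each of the 6 contrasts between groups was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on all 16 samples, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05. Errors of log2 changes are standard errors of that model, and intervals are its 95% confidence intervals. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

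The array numbers in the labels fall into 2 ranges, called slide series A and B here. Series A holds all control and oleic acid samples and elaidic acid replicates 2 and 4. Series B holds all stearic acid samples and elaidic acid replicates 1 and 3. Each contrast was therefore also fitted with slide series as a block. With that block, elaidic acid against control or oleic acid is the difference within series A (2 samples against 4), and elaidic acid against stearic acid is the difference within series B (2 against 4). Stearic acid shares no series with control or oleic acid, so that its blocked contrasts with them run through the elaidic acid samples.

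A total of 26 gene lists were written down with their members, and tested with camera in limma with its preset correlation of 0.01, adjusted over the lists. Each call was tested again with camera's estimated correlation and with fry. A list gene was represented by its probe with the highest mean over all samples. Cholesterol synthesis was the primary list. The mean log2 value of a list in each sample was compared between groups with an exact permutation test, two-sided. With 4 samples against 4 the smallest p such a test can give is 0.0286, and with 2 against 4 it is 0.0667. The genes named in each contrast were the 6 largest rises and the 6 largest falls among called probes with 1 symbol whose groups did not overlap. Where a direction had none, the 3 probes of smallest p were named as values that did not pass. Up to 4 members of smallest p were named for each list described, and SQLE, CPT1A, PDK4, ADFP and ANGPTL4 were always named in the contrasts with control and in elaidic acid against oleic acid. HMGCS1 and FASN, also on that fixed list of names, have no probe of that symbol in the table and were not analysed here, and some other items are not reported here. INSIG1 and SCD each had values at or below 0, in 2 samples and 1 sample, and were left out of the test. The lists, the naming rule, the tests of the comparisons and most alternatives were set before the data were examined.

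The model was tested on simulated data, in 20 simulations with 200 of 22939 probes changed. For elaidic acid against control it recovered 13.8% of probes changed 2-fold and 63.3% of those changed 4-fold, and 5.38% of the calls were false. With the slide series block these shares were 5.80%, 50.7% and 5.48%. The simulated values had independent noise and no slide series difference. The share of false calls may therefore differ in the real arrays, above all without the block. Alternatives covered the normalisation, dim probes, 1 probe per gene, a minimum change of 1.5-fold, an intensity trend, robust variances, array weights, blocks for replicate number and slide series, fits on subsets of the samples, and leaving out each sample in turn. An offset of 50, cyclic loess, the filter on the dimmest 50% together with the slide series block, leaving aside the 2 dimmest arrays, and all alternatives of the cell cycle list were chosen after seeing the data.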

Results

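Gene expression in HepG2 cells, a human liver tumour line that keeps many functions of hepatocytes, was compared after 7 days with 1 of 3 fatty acids of the same chain length or with none. Oleic acid has a cis double bond, elaidic acid has the trans double bond at the same position, and stearic acid is saturated. There were 4 biological replicates each of control, oleic acid, elaidic acid and stearic acid. Median intensity per array was 41.2 ± 22.5 in control, 34.7 ± 13.8 with oleic acid, 42.4 ± 15.8 with elaidic acid and 57.0 ± 13.2 with stearic acid (SD, n = 4 each). The series title names elaidic acid, the common dietary trans fat, as its subject, so that the contrasts with elaidic acid come first.

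The arrays separated by slide series more than by fatty acid. The first principal component held 47.3% of the variance, and slide series accounted for a share of 0.818 of it against 0.645 for the 4 groups. The pair of elaidic acid samples hybridised in series B lay with the stearic acid samples of that series, at correlations between 0.959 and 0.963, while their correlations with the other elaidic acid samples were between 0.893 and 0.913. Median intensity was 36.2 ± 16.05 in series A (SD, n = 10) and 56.6 ± 10.3 in series B (SD, n = 6). Values with slide series as a block are therefore given for the gene lists described and for most named genes.

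**Figure D1:**
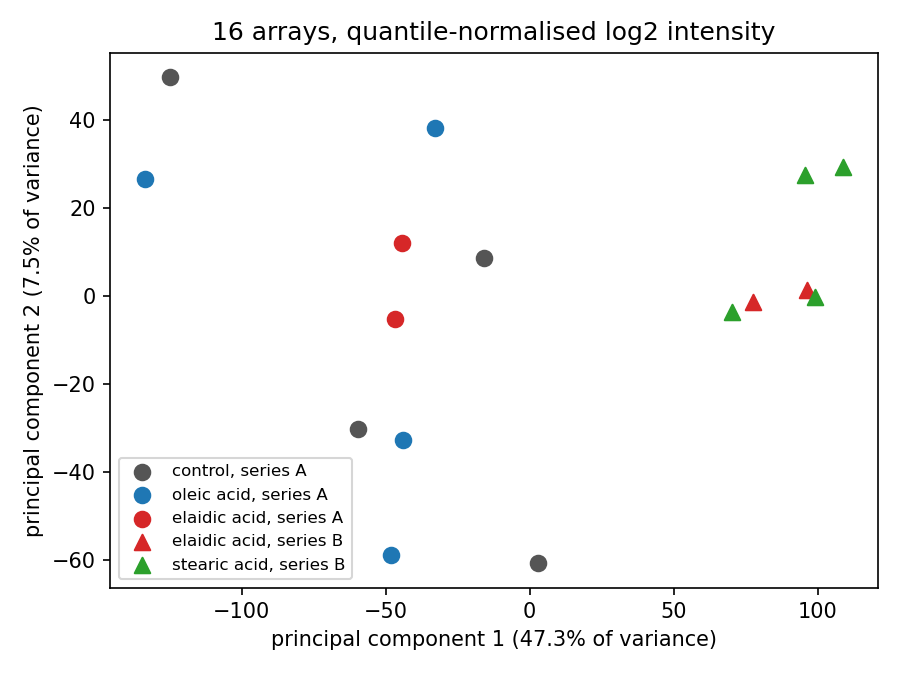
Samples on principal components 1 (47.3% of the variance) and 2 (7.54%) of the normalised log2 intensities, 1 point per array, coloured by group and shaped by slide series. The 6 arrays of series B, with elaidic or stearic acid, lie at the right, apart from the 10 arrays of series A.

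With elaidic acid, genes of cholesterol synthesis rose together against control. All 16 tested members of the list were higher, with a median log2 change of 0.95 (camera adjusted p = 5.6e-13, and adjusted p = 0.0091 with an estimated correlation). CYP51A1, the lanosterol demethylase (probe PH_hs_0033255), rose by 1.59 ± 0.21 (SE, n = 4 per group; adjusted p = 0.0038). SQLE, the squalene epoxidase, rose by 1.39 ± 0.26, and NSDHL, which acts in the removal of methyl groups from sterols, rose by 1.07 ± 0.21. SC5DL, a late sterol desaturase, had a change of 1.32 ± 0.29 that did not pass (adjusted p = 0.078). Over all probes 3 members of the list passed, and 12 passed when adjusted over the list alone. A second, dimmer probe of CYP51A1 had a change of -0.31 and did not pass. The mean log2 level of the list was 9.73 ± 0.29 with elaidic acid and 8.74 ± 0.18 in control (SD, n = 4), and every elaidic acid sample was above every control sample (exact permutation p = 0.0286). The mean was 0.75 higher within series A, with both elaidic acid samples above all control samples (exact permutation p = 0.0667). That p is the smallest that 2 samples against 4 can give. Within slide series A the median change was 0.83, again with 16 of 16 members higher (camera adjusted p = 1.3e-12, and adjusted p = 0.0090 with an estimated correlation). There 0 members passed limma over all probes and 8 passed when adjusted over the list alone, with CYP51A1 at 1.36 ± 0.23, SQLE at 1.03 ± 0.27, NSDHL at 1.03 ± 0.25 and SC5DL at 0.99 ± 0.33.

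**Figure D2:**
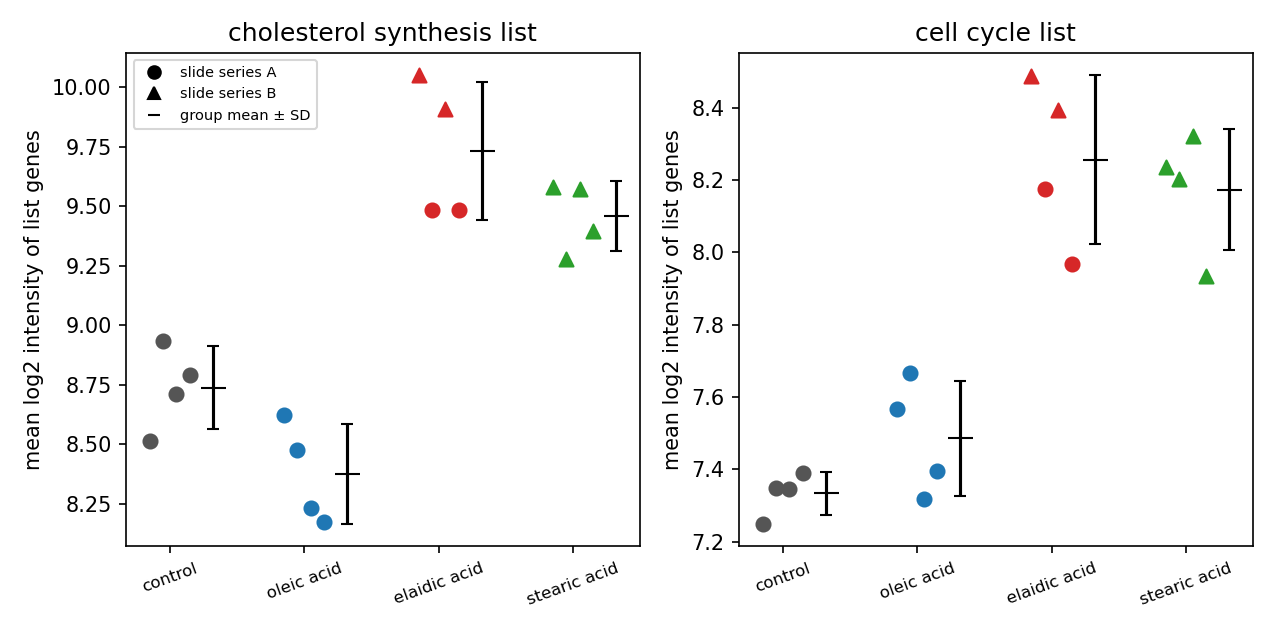
Mean log2 intensity of the cholesterol synthesis list (left) and the cell cycle list (right) in each sample, with slide series A as circles and B as triangles, and bars for the group mean and SD (n = 4). In both lists the 4 elaidic acid samples lie above the 4 control and the 4 oleic acid samples, and the elaidic acid samples of series B lie above those of series A.

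Genes of fatty acid synthesis and of lipid droplets had higher medians with elaidic acid as well. Over all samples the medians of common reference genes and cytosolic ribosomal proteins, given below, were at least as high. In the list of fatty acid synthesis and desaturation 14 of 16 members were higher, with a median of 0.41 (camera adjusted p = 1.7e-04, and adjusted p = 0.0091 with an estimated correlation). Its member ELOVL6, a fatty acid elongase, rose by 1.58 ± 0.27 (SE, n = 4 per group), while ACSS2, which makes acetyl-CoA from acetate, had a change of 2.28 ± 0.50 (adjusted p = 0.073) and PNPLA3, a lipase of lipid droplets, one of 0.71 ± 0.24 (adjusted p = 0.22). Of the list, 1 member passed over all probes and 4 passed when adjusted over the list alone. In the lipid droplet and triglyceride list 13 of 14 members were higher, with a median of 0.52 (camera adjusted p = 2.9e-05, and adjusted p = 0.014 with an estimated correlation). No single member passed limma over all probes and 3 passed when adjusted over the list alone. Its values of smallest p were 0.73 ± 0.18 for DGAT2 and 0.67 ± 0.22 for DGAT1, both enzymes of the last step of triglyceride synthesis, and 1.13 ± 0.35 for LPIN1, a phosphatidate phosphatase. Within series A the medians were 0.32 for fatty acid synthesis (adjusted p = 0.030 with an estimated correlation) and 0.40 for lipid droplets (adjusted p = 0.034 with an estimated correlation), and ELOVL6 was at 1.54 ± 0.33 there, where it did not pass (adjusted p = 0.13). The mean of each list was 0.39 higher there (exact permutation p = 0.133 and p = 0.0667). The mean log2 levels of reference genes there were 7.36 and 7.40 with elaidic acid, inside the control range of 6.96 to 7.86. ADFP, a coat protein of lipid droplets, had a change of 0.46 ± 0.21, CPT1A, which brings fatty acids to mitochondrial oxidation, 0.21 ± 0.21, PDK4, a kinase that restrains pyruvate oxidation, -0.32 ± 0.68, and ANGPTL4, an inhibitor of lipoprotein lipase, -0.46 ± 0.27, and none of these 4 passed. Within series A these 4 values were 0.31, 0.43, -1.05 and -0.15, and without elaidic acid replicate 2 the value of PDK4 was 0.48.

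Cell cycle genes also rose with elaidic acid. Of 24 tested members 20 were higher, with a median log2 change of 0.81 (0.38 to 0.95 over the alternatives; camera adjusted p = 3.1e-12, and adjusted p = 0.0029 with an estimated correlation). CCNB2, the mitotic cyclin B2 (probe PH_hs_0011508), rose by 2.52 ± 0.27 (SE, n = 4 per group; adjusted p = 0.0019), RRM2, a subunit of ribonucleotide reductase, by 1.94 ± 0.23, TK1, the cytosolic thymidine kinase, by 1.88 ± 0.30, and MKI67, the proliferation marker Ki-67, by 1.52 ± 0.21. Over all probes 5 members passed, and 13 passed when adjusted over the list alone. Within series A the median was 0.69 with 19 of 24 members higher (adjusted p = 0.0047 with an estimated correlation), 12 members passed when adjusted over the list alone, and 2 passed over all probes, CCNB2 at 2.62 ± 0.33 and RRM2 at 1.97 ± 0.28, while TK1 was at 2.04 ± 0.36 and MKI67 at 1.39 ± 0.24. Among the 6 largest rises of single probes, GINS2, a subunit of the replicative helicase, rose by 3.02 ± 0.50, CENPA, the histone of centromeres, by 2.93 ± 0.53, CEP55, which acts in the last step of cell division, by 2.80 ± 0.46, and OIP5, which helps to load CENPA, by 2.73 ± 0.38. A second, brighter probe of GINS2 had a change of -0.33 and a second, dimmer probe of CENPA one of -0.16, and neither passed. GINS2 at 2.52 ± 0.59, CENPA at 1.91 ± 0.48, CEP55 at 2.12 ± 0.49 and OIP5 at 2.47 ± 0.45 did not pass within series A.

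Coagulation genes, which hepatocytes secrete as plasma proteins, also rose with elaidic acid, by a median of 0.85 with 13 of 17 members higher (camera adjusted p = 5.2e-06, and adjusted p = 0.017 with an estimated correlation). KNG1, the kininogen gene (probe PH_hs_0004485), rose by 1.91 ± 0.22 (SE, n = 4 per group; adjusted p = 0.0025) and by 1.93 ± 0.26 within series A (adjusted p = 0.026). SERPINF2, the plasmin inhibitor, had a change of 0.85 ± 0.18, F12, a coagulation factor, 0.82 ± 0.22, and F10, another one, 1.36 ± 0.41, none of which passed. Over all probes 1 member passed, and 10 passed when adjusted over the list alone. Within series A the median of the list was 0.63 (adjusted p = 0.039 with an estimated correlation), and its mean was 0.47 higher (exact permutation p = 0.133). The fewer falls included OTOA, an inner ear protein gene at the lowest end of the intensity range, by -3.37 ± 0.56, PDE2A, a cyclic nucleotide phosphodiesterase, by -1.96 ± 0.34, SYTL2, which acts in vesicle transport, by -1.41 ± 0.27, and ADAM9, a membrane protease, by -1.17 ± 0.20. UTP6, which acts in ribosomal RNA processing, rose by 2.46 ± 0.48, also from a dim probe. Within series A these 5 values were -3.63 ± 0.70, -1.99 ± 0.43, -1.71 ± 0.31, -1.02 ± 0.23 and 2.36 ± 0.60, and none passed.

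In all, limma called 74 probes between elaidic acid and control, 70 higher and 4 lower, and 1492 of 22939 probes (6.50%) did not overlap between the groups, where chance gives 2.86%. The 2.86%, here and below, assumes that the arrays of both groups are interchangeable, which slide series breaks where it differs. An excess over it is therefore by itself no measure of a fatty acid effect. With slide series as a block 9 probes were called, 6 higher and 3 lower, of which 6 were among the 74. The count was 0 without normalisation and 0 when the model held only these 2 groups, and leaving out 1 sample gave 33 without control replicate 1, 38 without control replicate 2, 36 without control replicate 3, 25 without elaidic acid replicate 1, 25 without elaidic acid replicate 3 and 115 without elaidic acid replicate 4. Of the 26 gene lists 15 passed camera, all higher, and 7 passed with an estimated correlation. Markers of other cell types had a median of -0.19, or 0.10 within series A, and did not pass (camera adjusted p = 0.28), and their mean was 0.31 lower (exact permutation p = 0.0571), or 0.33 lower within series A (exact permutation p = 0.20). Cytosolic ribosomal proteins had a mean 0.84 higher, with every elaidic acid sample above every control sample (exact permutation p = 0.0286), or 0.43 higher within series A (exact permutation p = 0.133), and camera adjusted p = 0.075 with an estimated correlation.

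With oleic acid, the cis isomer, all 16 members of the cholesterol synthesis list had lower values than in control. Their median was -0.33 (camera adjusted p = 6.5e-06), a call that was lost at adjusted p = 0.18 with an estimated correlation and at adjusted p = 0.29 with fry. The mean log2 level of the list was 8.38 ± 0.21 with oleic acid against 8.74 ± 0.18 in control (SD, n = 4; exact permutation p = 0.0571). No member passed by itself in limma, and 0 passed when adjusted over the list alone. SC5DL had a change of -0.61 (95% interval -1.23 to 0.01), EBP, the sterol isomerase, one of -0.46 (-0.92 to 0.00), and SQLE one of -0.33 ± 0.26 (SE, n = 4 per group). The cell cycle list rose by a median of 0.17 with 17 of 24 members higher (0.01 to 0.38 over the alternatives; camera adjusted p = 0.014, and adjusted p = 0.18 with an estimated correlation), and CCNB2 had a change of 0.84 (0.28 to 1.41) that did not pass. ADFP had a change of 0.31 (-0.14 to 0.75) and CPT1A one of 0.37 (-0.09 to 0.82).

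All oleic acid and control samples were in series A. Across all probes limma called 0 of 22939 between them, with 602 at an unadjusted p under 0.05 and 283 (1.23%) that did not overlap, where chance gives 2.86%. With slide series in the model the count was again 0, with 759 at an unadjusted p under 0.05. Among the 3 probes of smallest p in each direction were OGG1, a DNA repair glycosylase, at 2.33 ± 0.37 (adjusted p = 0.29), and SMARCAD1, a chromatin remodeller, at -5.45 ± 1.36 (adjusted p = 1.0). NDUFA12L and RBM33 were the other probes of smallest p above control, at 1.34 ± 0.31 and 1.31 ± 0.32, and C9orf61 and SLCO6A1 those below it, at -1.87 ± 0.39 and -1.90 ± 0.44 (SE, n = 4 per group). None of these 6 passed.

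The trans and the cis isomer differed most in cholesterol synthesis. At matched dose and time all 16 members of that list were higher with elaidic than with oleic acid, by a median log2 difference of 1.26 (camera adjusted p = 1.2e-17, and adjusted p = 0.0027 with an estimated correlation). CYP51A1 was higher by 1.78 ± 0.21 (SE, n = 4 per group; adjusted p = 0.0032), SC5DL by 1.93 ± 0.29, SQLE by 1.72 ± 0.26 and NSDHL by 1.44 ± 0.21, and all 4 passed. Over all probes 5 members passed, and 13 passed when adjusted over the list alone. The mean log2 level of the list was 1.36 higher with elaidic acid over all samples (exact permutation p = 0.0286). Within series A the difference of means was 1.11, with both elaidic acid samples above the 4 oleic acid samples (exact permutation p = 0.0667, the smallest that 2 against 4 can give). The median within series A was 1.13, again with 16 of 16 members higher (adjusted p = 0.0010 with an estimated correlation), and CYP51A1 passed there at 1.55 ± 0.23 (adjusted p = 0.036), while SC5DL at 1.60 ± 0.33, SQLE at 1.36 ± 0.27 and NSDHL at 1.41 ± 0.25 did not.

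**Figure D3:**
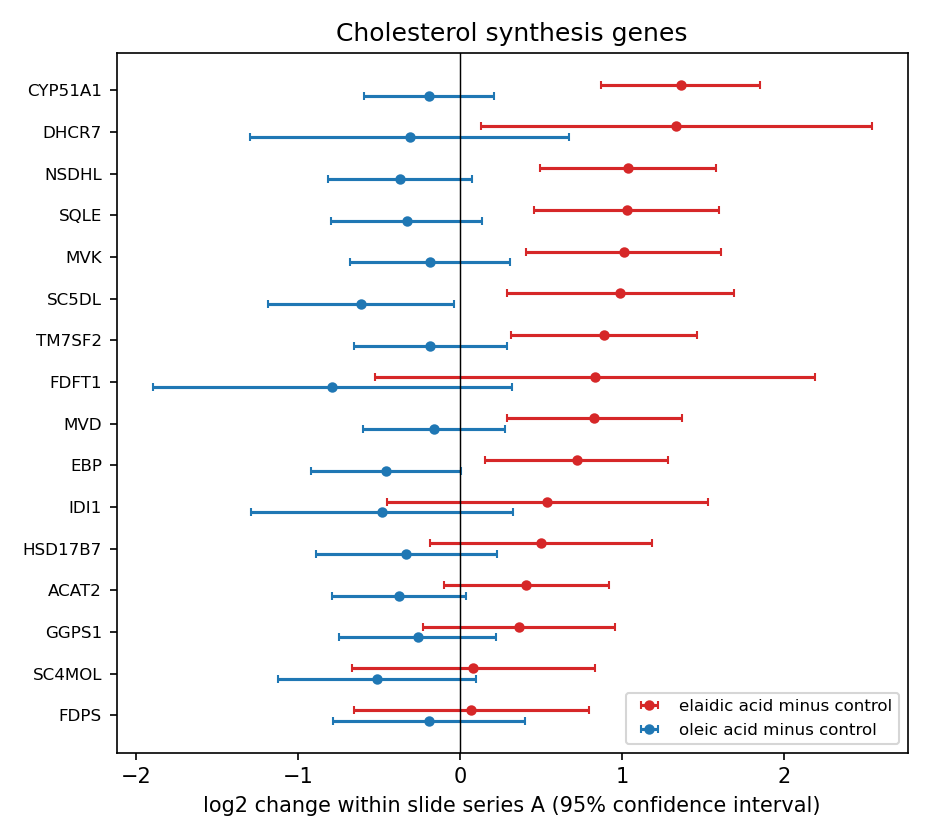
Log2 change of the 16 cholesterol synthesis genes within slide series A, with 95% confidence intervals, for elaidic acid (n = 2) and oleic acid (n = 4) against control (n = 4). All 16 estimates lie above 0 with elaidic acid and below 0 with oleic acid, and 8 of the elaidic acid estimates passed when adjusted over the list alone.

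The 4 further lists described above for elaidic acid and control also passed between the isomers. Fatty acid synthesis genes were higher with elaidic acid by a median of 0.63 (adjusted p = 0.0027 with an estimated correlation), with ELOVL6 at 1.76 ± 0.27 and ACSS2 at 2.60 ± 0.50 past the threshold. Over all probes 2 members of that list passed, and 4 passed when adjusted over the list alone. Lipid droplet genes were higher by a median of 0.49 (adjusted p = 0.022 with an estimated correlation), with LPIN1 at 1.81 ± 0.35, the 1 member that passed over all probes, and 3 that passed when adjusted over the list alone. Cell cycle genes were higher by 0.84 (0.27 to 1.15 over the alternatives; adjusted p = 0.0073 with an estimated correlation), with CCNB2 at 1.68 ± 0.27, RRM2 at 1.32 ± 0.23 and MKI67 at 1.05 ± 0.21 as the 3 members that passed over all probes, and 10 that passed when adjusted over the list alone. Coagulation genes were higher by 0.63 (adjusted p = 0.028 with an estimated correlation), with KNG1 at 1.82 ± 0.22 past the threshold and 7 members that passed when adjusted over the list alone. Within series A these 4 medians were 0.46, 0.43, 0.66 and 0.47, each past the threshold with an estimated correlation, and KNG1 passed there at 1.85 ± 0.26 (adjusted p = 0.036), while ELOVL6 at 1.72, ACSS2 at 1.88, LPIN1 at 1.45, CCNB2 at 1.77, RRM2 at 1.36 and MKI67 at 0.91 did not. FABP1, the liver fatty acid binding protein, was higher by 2.68 ± 0.52 and its other, brighter probe by 2.48, or 2.08 and 2.02 within series A, where neither passed. DNAJB9, a cofactor of chaperones in the endoplasmic reticulum, was higher by 2.38 ± 0.40 and by 1.55 ± 0.33 within series A, where it did not pass (adjusted p = 0.21). CENPA was higher by 3.001 ± 0.53, or 1.98 ± 0.48 within series A (adjusted p = 0.27), and OIP5 by 2.75 ± 0.38. C9orf61, a gene without a clear function, was higher by 2.36 ± 0.39. The largest differences below 0 were -3.58 ± 0.56 for OTOA, -1.67 ± 0.31 for a dim probe of NDUFA12L and -1.56 ± 0.27 for SYTL2, while a bright probe of NDUFA12L had a difference of 0.82 that did not pass. OIP5 at 2.49, C9orf61 at 2.70, OTOA at -3.85, that dim probe at -1.63 and SYTL2 at -1.87 did not pass within series A. For ADFP the difference between the isomers was 0.16 (95% interval -0.29 to 0.60), for CPT1A -0.15 (-0.61 to 0.30) and for ANGPTL4 -0.43 (-1.003 to 0.15), and none of these 3 passed. The sign for CPT1A turned within series A, at 0.07, and without normalisation, at 0.13.

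Between the isomers limma called 73 probes, 69 higher and 4 lower with elaidic acid, and 1624 probes (7.08%) did not overlap, where chance gives 2.86%. With slide series as a block 5 probes were called, 4 higher and 1 lower, of which 4 were among the 73. The count was 0 when the model held only these 2 groups, and leaving out 1 sample gave 39 without oleic acid replicate 2, 13 without oleic acid replicate 3, 23 without oleic acid replicate 4, 3 without elaidic acid replicate 1, 111 without elaidic acid replicate 2, 7 without elaidic acid replicate 3 and 191 without elaidic acid replicate 4. Of the 26 lists 17 passed camera and 9 passed with an estimated correlation. The other 4 of the 9 were lipoproteins (median 0.65), the unfolded protein response (0.86), acute phase (1.01) and oxidative phosphorylation (0.65), and of these the last 2 did not pass within series A with an estimated correlation (adjusted p = 0.076 and adjusted p = 0.095).

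Elaidic and stearic acid differ by the trans double bond. The cholesterol synthesis list had a median difference of 0.34 with 11 of 16 members higher with elaidic acid, and it did not pass (camera adjusted p = 0.072). Over all probes 0 members passed limma, and 3 passed when adjusted over the list alone. Within series B, where both acids were hybridised, the median was 0.59 with 13 of 16 members higher, and it passed camera (adjusted p = 1.7e-06) but was lost at adjusted p = 0.083 with an estimated correlation. The mean log2 level of the list there was 9.98 ± 0.10 with elaidic acid (SD, n = 2) and 9.46 ± 0.15 with stearic acid (SD, n = 4), with both elaidic acid samples above all 4 (exact permutation p = 0.0667, the smallest possible). Without normalisation the median turned to -0.15. NSDHL had a difference of 0.70 (95% interval 0.25 to 1.15), MVD, an enzyme of the mevalonate pathway, one of 0.94 (0.37 to 1.52), and FDPS, the farnesyl diphosphate synthase, one of 0.84 (0.25 to 1.43), and none of these 3 passed. Within series B they were at 0.73, 0.46 and 0.93. The cell cycle list had a median difference of 0.18 (camera adjusted p = 0.24), 0.29 within series B (camera adjusted p = 0.010, and adjusted p = 0.18 with an estimated correlation) and -0.14 without normalisation.

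Some single genes were called between elaidic and stearic acid in the model without slide series, but not within series B. KNG1 was higher with elaidic acid by 1.34 ± 0.22 (SE, n = 4 per group; adjusted p = 0.038), as was PCOLCE, an enhancer of procollagen processing, by 1.503 ± 0.23, TGFA, a growth factor for the EGF receptor, by 1.34 ± 0.27, PIF1, a DNA helicase, by 1.59 ± 0.32, ALDH3B2, an aldehyde dehydrogenase, by 1.41 ± 0.26, and TMEM132E, a membrane protein gene, by 1.56 ± 0.31. Lower with elaidic acid were AQP3, a water and glycerol channel, by -1.79 ± 0.26, PRDX4, a peroxiredoxin of the endoplasmic reticulum, by -2.29 ± 0.37, TPM4, a tropomyosin, by -2.37 ± 0.41, MTX1, a protein of mitochondrial import, by -2.03 ± 0.39, CAPNS1, the small calpain subunit, by -1.86 ± 0.33, and OTOA by -2.89 ± 0.56. Within series B the 6 genes higher with elaidic acid were at 1.31 for KNG1, 1.55 for PCOLCE, 0.93 for TGFA, 1.77 for PIF1, 1.02 for ALDH3B2 and 1.10 for TMEM132E, the lower ones were at -1.41 for AQP3, -1.66 for PRDX4, -1.71 for TPM4, -1.68 for MTX1, -1.79 for CAPNS1 and -2.62 for OTOA, and none of the 12 passed. Limma called 91 probes, 20 higher and 71 lower, and 2719 (11.9%) did not overlap, where chance gives 2.86%. With slide series as a block 1 probe was called, lower with elaidic acid and not among the 91. The count was 49 without elaidic acid replicate 1 and 0 without any 1 of elaidic acid replicates 2, 3 and 4 or stearic acid replicates 1, 2, 3 and 4. The share of higher probes was 22.0%, and with median centring, where 129 probes were called, it was 6.98%. Of the 26 lists 5 passed camera and 0 passed with an estimated correlation.

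Stearic acid samples differed from control in 6825 probes, in a contrast that slide series follows completely. Among cholesterol synthesis genes 13 of 16 were higher, with a median of 0.99 (0.24 to 1.51 over the alternatives; camera adjusted p = 0.0011), a call that was lost at adjusted p = 0.17 with an estimated correlation. CYP51A1 rose by 1.28 ± 0.21 (SE, n = 4 per group) and by 0.81 ± 0.32 with slide series as a block, where it did not pass (adjusted p = 0.55), SQLE rose by 1.28 ± 0.26 (0.56 ± 0.38 with the block), EBP by 1.03 ± 0.22 (0.96 ± 0.37) and MVK, the mevalonate kinase, by 1.02 ± 0.23 (1.15 ± 0.40). A dimmer probe of CYP51A1 had a change of -0.90 and did not pass. Over all probes 9 members were called, and 9 higher and 1 lower when adjusted over the list alone. With the block the median was 0.29 and did not pass (camera adjusted p = 0.16). Genes of the ATF4 and amino acid response rose by a median of 1.38 with 18 of 21 higher (camera adjusted p = 1.1e-05, and adjusted p = 0.16 with an estimated correlation), with the serine synthesis enzymes PHGDH at 1.51 ± 0.22 and PSAT1 at 2.07 ± 0.37, the transcription factor ATF5 at 2.29 ± 0.34 and the pseudokinase TRIB3 at 1.45 ± 0.26. Oxidative phosphorylation genes rose by a median of 1.08 with 16 of 22 higher (camera adjusted p = 2.4e-04, and adjusted p = 0.13 with an estimated correlation), with the ATP synthase subunits ATP5O at 1.75 ± 0.27 and ATP5B at 1.31 ± 0.21 and the cytochrome oxidase subunits COX5A at 3.05 ± 0.48 and COX6C at 1.49 ± 0.26. Cell cycle genes rose by 0.91 with 18 of 24 higher (camera adjusted p = 3.2e-04, and adjusted p = 0.13 with an estimated correlation), with CCNB2 at 1.56 ± 0.27, RRM2 at 1.36 ± 0.23, BIRC5, a regulator of mitosis and survival, at 1.60 ± 0.27 and PCNA, the replication clamp, at 2.22 ± 0.38. With the block the medians of these 3 lists were 0.47, 0.49 and 0.45, with adjusted p = 0.62, adjusted p = 0.21 and adjusted p = 0.21 with an estimated correlation. When adjusted over the list alone 14, 11 and 12 members of these lists were higher and 1 of each was lower. With the block PHGDH was at 1.28, PSAT1 at 0.89, ATF5 at 2.20, TRIB3 at 1.16, ATP5O at 1.10, ATP5B at 0.95, COX5A at 1.503, COX6C at 0.83, CCNB2 at 1.75, RRM2 at 1.44, BIRC5 at 1.05 and PCNA at 1.19, and none passed. Common reference genes, with a mean log2 level 1.15 higher than in control, and cytosolic ribosomal proteins, 1.56 higher, differed by more than the cholesterol synthesis list at 0.72 and the cell cycle list at 0.84, and markers of other cell types were 0.43 lower (exact permutation p = 0.0286 for each list, the smallest possible). With the block the median changes of the genes of these lists, a measure other than the means above, were 0.04 for reference genes, 0.85 for ribosomal proteins and -0.15 for other markers. ADFP rose by 0.63 ± 0.21 (adjusted p = 0.036), or 0.33 ± 0.34 with the block.

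The largest single changes with stearic acid came from probes below the median intensity, some of them at background in single samples, so that the size of these changes is uncertain. CSNK1A1, a casein kinase, rose by 4.99 ± 1.77, C9orf78 by 4.57 ± 0.98, HSDL2 by 4.39 ± 1.05, CNBP, a nucleic acid binding protein, by 4.12 ± 1.29, PRDX2, a peroxiredoxin, by 4.10 ± 0.62 and C3orf39 by 3.95 ± 0.85 (SE, n = 4 per group). With the block these changes were 2.76 ± 3.10, 0.67 ± 1.21, 1.09 ± 1.55, 0.36 ± 1.98, 2.28 ± 0.94 and -0.01 ± 0.82, and none passed. Without control replicate 1, where CSNK1A1 was at a log2 intensity of -4.59, the change of CSNK1A1 was 2.32 and that of CNBP 2.69. A bright probe of CNBP had a change of -0.21. DNTT, a polymerase of lymphocytes, fell by 3.003 ± 0.73, SLC10A5, a transporter of the bile acid carrier family, by -2.79 ± 0.71, SNX19 by 2.56 ± 0.53, SOX6, a transcription factor, by 2.50 ± 0.62 and OR5I1, an olfactory receptor, by 2.48 ± 0.69. With the block DNTT was at -2.70, SLC10A5 at -2.03, SNX19 at -1.87, SOX6 at -1.85 and OR5I1 at 0.01 ± 0.93, none of which passed, and a second probe of SLC10A5 one of -0.07.

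Limma called 6825 probes between stearic acid and control, 3432 higher and 3393 lower, and 8629 (37.6%) did not overlap, where chance gives 2.86%. With slide series as a block limma called 0, with 1710 at an unadjusted p under 0.05, and 5738 of the 6825 kept their direction, at a median ratio of 0.336 of their change. The blocked contrast reuses the stearic acid and control samples that selected these probes, so that part of this agreement is built in. Leaving out 1 sample gave 3576 without control replicate 1, 4247 without control replicate 3, 3571 without stearic acid replicate 1, 4108 without stearic acid replicate 3 and 4468 without stearic acid replicate 4. The share of higher probes was 50.3%, and without normalisation it was 92.1% of 3099. The median of all probes in this contrast was -0.18 with normalisation and 0.26 without it. Of the 26 lists 15 passed camera and 0 passed with an estimated correlation.

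Oleic and stearic acid, which differ by the cis double bond, were also hybridised in different slide series. Cholesterol synthesis genes were lower with oleic acid, by a median of -1.34 with 14 of 16 lower (camera adjusted p = 1.8e-05, and adjusted p = 0.13 with an estimated correlation). Of these, SQLE was lower by -1.61 ± 0.26, SC5DL by -1.62 ± 0.29, EBP by -1.49 ± 0.22 and CYP51A1 by -1.47 ± 0.21 (SE, n = 4 per group), 12 members passed over all probes and 13 when adjusted over the list alone. A dimmer probe of CYP51A1 was higher by 1.26 and passed. With the block the median was -0.65 (camera adjusted p = 6.7e-05, and adjusted p = 0.22 with an estimated correlation), 0 members passed limma over all probes, and these 4 genes were at -0.89 ± 0.38, -0.96 ± 0.47, -1.42 ± 0.37 and -1.01 ± 0.32. Genes of the ATF4 and amino acid response had a median of -1.46 (adjusted p = 0.14 with an estimated correlation), with GDF15, a stress-induced secreted factor, at -2.18 ± 0.34, and oxidative phosphorylation genes one of -1.19 (adjusted p = 0.13 with an estimated correlation), with COX5A at -2.98 ± 0.48. The cell cycle list had a median of -0.56 (adjusted p = 0.14 with an estimated correlation), with PCNA at -2.53 ± 0.38, MCM2, a helicase subunit, at -2.22 ± 0.51 and E2F1, a transcription factor of the cell cycle, at 1.15 ± 0.30. When adjusted over the list alone 15, 14 and 11 members of these lists were lower, and 2, 0 and 1 were higher. With the block GDF15 was at -1.63, COX5A at -1.44, PCNA at -1.51, MCM2 at -0.41 ± 0.69 and E2F1 at 0.05 ± 0.38.

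The largest single differences between oleic and stearic acid again came from probes below the median intensity, and their size is uncertain. SMARCAD1 was lower with oleic acid by -7.66 ± 1.36, HIGD1A, a mitochondrial protein of the hypoxia response, by -4.71 ± 1.04, FBXL12, a subunit of a ubiquitin ligase, by -4.63 ± 1.32, PKP3, a desmosome protein, by -4.42 ± 1.65, LSM4, which acts in RNA splicing, by -4.08 ± 0.83 and DLC1, a tumour suppressor gene, by -4.03 ± 0.76 (SE, n = 4 per group). With the block these were -2.55, -3.16, -1.99, -2.15, -1.87 and -1.26, and none passed. Brighter probes of HIGD1A and LSM4 had differences of -1.62 and 0.34 that did not pass. FBXL12 was at -2.94 without oleic acid replicate 2, and PKP3 at -1.92 without oleic acid replicate 4, where it was at background with a log2 intensity of -4.49. Higher with oleic acid were ZNHIT1, of a chromatin remodelling complex, by 3.52 ± 1.04, CHRNA2, a nicotinic receptor subunit, by 3.14 ± 0.67, RNF24, a membrane ring finger protein, by 2.86 ± 0.86, SNX19, a sorting nexin, by 2.65 ± 0.53 and IGFL3, of an insulin-like growth factor family, by 2.51 ± 0.59. With the block these 5 were at 2.46, 2.80, 2.41, 1.97 and 0.50, none of which passed, and ZNHIT1 was at 2.21 without stearic acid replicate 4.

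Limma called 9057 probes between oleic and stearic acid, 4827 higher and 4230 lower with oleic acid, and 10261 (44.7%) did not overlap, where chance gives 2.86%. With slide series as a block limma called 0, with 1513 at an unadjusted p under 0.05. The count was 4766 without oleic acid replicate 4 and 5247 without stearic acid replicate 1. The share of higher probes was 53.3%, and without normalisation it was 5.87% of 5125. Leaving out the normalisation moved the median of all probes from 0.21 to -0.39 here, from 0.07 to -0.28 in elaidic against stearic acid, from -0.13 to 0.12 in elaidic against oleic acid, from -0.10 to 0.01 in elaidic acid against control and from 0.01 to -0.12 in oleic acid against control. Of the 26 lists 17 passed camera and 0 passed with an estimated correlation.

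The contrasts with control shared their control samples, which alone gives a correlation across probes near 0.5. Across all probes the changes with elaidic and with stearic acid correlated at 0.809, against 0.497 in simulated groups without an effect that shared only the control samples. With the control samples split between the contrasts the median correlation was 0.551 (0.305 to 0.616 over the splits). The changes with elaidic and with oleic acid correlated at 0.175, against 0.4998 simulated. Their median was -0.14 with the control samples split (-0.47 to 0.07 over the splits). Those with oleic and stearic acid correlated at 0.01, against 0.496 simulated. Probes are not independent replicates, and part of the elaidic acid samples shared slide series B with stearic acid. The simulated noise was independent between probes, while in the arrays 1 component held 47.3% of the variance. The simulated values are therefore no firm reference for these correlations.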

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

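The tests of the slide series difference for all 3 patterns below, and of stearic acid itself, were chosen after the result was seen. Of 275 groups of 4 samples, 18 held 1 sample far from the other 3, measured as its gap to the nearest sample over the range of the group. Chance gives about 1 in 20 groups, which is 5%. Control replicate 1, the array of lowest median intensity (19.95), stood apart for F10 (0.876), CSNK1A1 (0.845), TRIB3 (0.941) and PSAT1 (0.887). Oleic acid replicate 4, the next dimmest (20.7), stood apart for ELOVL6 (0.918), LPIN1 (0.864), OGG1 (0.845), PKP3 (0.979) and LSM4 (0.938), and oleic acid replicate 1 for ANGPTL4 (0.947). Elaidic acid replicate 4 stood apart for ADAM9 (0.873) and F12 (0.909), and elaidic acid replicate 2 for DGAT1 (0.861). Stearic acid replicate 2 stood apart for the mean of the oxidative phosphorylation list (0.892), TRIB3 (0.8291), MTX1 (0.894) and CAPNS1 (0.889), and stearic acid replicate 1 for MVD (0.944).

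Across all probes the difference between stearic acid and control, with 6825 called, correlated at 0.716 with that between the elaidic acid samples of series B and of series A, and 6305 of the 6825 (92.4%) had the same sign there, so that a difference between slide series may account for much of it. The slope of each probe on array brightness within groups correlated with it at 0.486, which lies between the bounds set for and against brightness and leaves that open. No series held both groups, and the blocked contrast runs through 2 elaidic acid samples in each series, where limma called 0 probes, with 1710 at an unadjusted p under 0.05. With an offset of 50 and the same block, an alternative chosen after seeing the data, it called 33, of which 32 were among the 6825, and 5 lists passed camera with the block but none with an estimated correlation. For most of the 6825 probes stearic acid itself cannot be told apart from slide series, and an effect of it on some stays open.

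The second pattern was the rise of cholesterol synthesis genes with elaidic acid over control. The tables argue against slide series as the whole cause, since the median change within series A was 0.83. Array brightness predicted a change of 0.0386 there, and the list median lay at percentile 100 of 10000 random lists of matched signal level, the highest of which was 0.447, against a shift of all genes of that level. An effect of elaidic acid itself on these genes is a hypothesis that stays open, with 2 elaidic acid samples in series A.

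The third pattern was the rise of cell cycle genes with elaidic acid over control. Within series A the median change was 0.69, array brightness predicted 0.00573, and the median lay at percentile 100 of matched random lists, the highest of which was 0.422. These values argue against the same 3 technical explanations. A difference in growth between the cultures, through elaidic acid or through their density, stays open and was not tested.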

How the results depend on the processing

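The offset of 50, cyclic loess, the dimmest 50% left out together with the slide series block, the 2 dimmest arrays left aside and all alternatives of the cell cycle list were chosen after seeing the data. The median change of cholesterol synthesis genes kept its direction and passed in all 24 alternatives for elaidic acid against control (0.76 to 1.12, adjusted p from 6.2e-15 to 0.0091) and against oleic acid (0.94 to 1.56, adjusted p from 3.1e-27 to 0.0027). The cell cycle median kept its direction and passed in the same alternatives but moved further, from 0.38 to 0.95 against control and from 0.27 to 1.15 against oleic acid, lowest with the offset and the slide series block. For stearic acid against control the cholesterol synthesis median was 0.44 with the offset, where it passed. Counts of probes moved as well, and the cause was not tested. In some alternatives fewer samples or probes entered. Of 4016 values of named genes 3125 counted as the same, 803 kept their direction but no longer passed, 66 kept it and newly passed, 11 moved and 11 reversed. The same were values that kept their direction and side of the threshold. They also included values that turned sign by less than the standard error where neither value passed. Moved values turned sign by more where neither passed, and reversed values turned sign where either passed. Signal over background limits the dim probes: 25.9% of all probes had a value at or below 0, were left out of the main fit and entered only with the offset.

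Counts are given here for elaidic acid against control, oleic acid and stearic acid in that order. They were 0, 2 and 0 without normalisation, 154, 126 and 223 with an intensity trend, 130, 128 and 222 without the dimmest 25%, 189, 180 and 294 without the dimmest 50%, 4656, 8953 and 1030 with array weights, and 224, 209 and 581 with an offset of 50. With only the 2 groups in the model they were 0, 0 and 0, and with one slide series only 0, 0 and 0, where fewer samples entered. Leaving the 2 dimmest arrays aside gave 41, 24 and 304, and the dimmest 50% left out with the slide series block 29, 14 and 0. Limma with the slide series block called 9, 5 and 1, and the offset with that block called 58, 24 and 64. For stearic acid against control and oleic against stearic acid, the counts were 3099 and 5125 without normalisation, 4161 and 5266 with 1 probe per gene, 0 and 0 with the slide series block, 0 and 0 with that block and the dimmest 50% left out, and 33 and 4 with that block and the offset. Stearic acid against control gave 10585 with array weights and 4459 without the 2 dimmest arrays, and oleic acid against control gave 1 with array weights. The array weights were 0.309 and 0.324 for elaidic acid replicates 2 and 4 of series A. They were 1.26 and 2.97 for elaidic acid replicates 1 and 3 of series B. The weighted elaidic acid group therefore leaned on series B. Its weighted counts against control and oleic acid cannot separate elaidic acid from slide series.

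The values gave no evidence that the replicate numbers pair the samples. Of 24 pairs of the same number 7 correlated above 0.1 (from -0.46 to 0.36, median -0.05), and 2 did after slide series was removed. With replicate as a block limma called 28, 4 and 0 probes for elaidic acid against control, oleic acid and stearic acid. With replicate and slide series blocks it called 0, 0 and 1, and 0 and 0 for stearic acid against control and oleic against stearic acid.

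With an estimated correlation 7, 0, 0, 9, 0 and 0 of the 26 lists passed for elaidic acid against control, oleic acid against control, stearic acid against control, elaidic against oleic, elaidic against stearic and oleic against stearic acid, and with the slide series block 5 lists passed for stearic acid against control and 7 for oleic against stearic acid. The cholesterol synthesis median no longer passed for oleic acid against control with an estimated correlation (-0.33, adjusted p = 0.18) or fry (-0.33, adjusted p = 0.29, the highest of its alternatives). It no longer passed for oleic against stearic acid with an estimated correlation (-1.34, adjusted p = 0.13). For stearic acid against control it did not pass with an estimated correlation (0.99, adjusted p = 0.17, the highest of its alternatives), the slide series block (0.29), that block with replicate (0.40), with the offset (0.24) or without the dimmest 50% (0.32). For elaidic against stearic acid, where adjusted p ran from 4.2e-08 to 0.46 over the alternatives, it newly passed with the mean of all probes of a gene (0.34), the offset (0.31), the slide series block (0.59), one slide series only (0.59), that block with replicate (0.56), with the offset (0.53) or without the dimmest 50% (0.59), and it was -0.15 without normalisation.

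Reversed for stearic acid against control were C3orf39 (-0.0130) and OR5I1 (0.00678) with the slide series block, HSDL2 (-0.57), CNBP (-0.53) and C3orf39 (-0.55) with replicate and slide series blocks, and C9orf78 (-0.14), HSDL2 (-0.17) and CNBP (-0.46) with the offset and the slide series block. Reversed for oleic against stearic acid were E2F1 (-0.0126) with replicate and slide series blocks, and FBXL12 (0.20) and MCM2 (0.20) with the offset and the slide series block.

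Leaving out 1 sample at a time gave 25 to 115 probes for elaidic acid against control, 3 to 191 against oleic acid, 0 to 49 against stearic acid, 0 to 0 for oleic acid against control, 3571 to 8213 for stearic acid against control and 4766 to 8520 for oleic against stearic acid, with the samples that moved a count named in the report. The cholesterol synthesis medians ran from 0.85 to 1.06, 1.14 to 1.43, 0.21 to 0.43, -0.47 to -0.26, 0.84 to 1.11 and -1.44 to -1.20 in that order. The median for elaidic against stearic acid passed without elaidic acid replicate 2 or 4 or stearic acid replicate 1 or 3.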

Other observations

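The list of further mitotic genes and its test, and the reading of the splits by the first principal component, were chosen after the result was seen. Beyond the groups in the report, the lists of lipoproteins (median log2 change 0.47; adjusted p = 0.046 with an estimated correlation) and of the unfolded protein response (0.61; adjusted p = 0.042) were higher with elaidic acid than in control. Within series A their medians were 0.38 and 0.28, and neither passed there with an estimated correlation (adjusted p = 0.095 and adjusted p = 0.10). Passing camera only with the preset correlation were fatty acid oxidation (0.58; adjusted p = 0.13 with an estimated correlation), PPAR-alpha targets (0.29; adjusted p = 0.18), ATF4 and amino acid response (0.76; adjusted p = 0.095), NRF2 and antioxidant genes (0.73; adjusted p = 0.13), acute phase (0.83; adjusted p = 0.075), hepatocyte identity (0.76; adjusted p = 0.13), oxidative phosphorylation (0.49; adjusted p = 0.062) and cytosolic ribosomal proteins (0.97; adjusted p = 0.075). The NRF2 median was -0.02 within series A.

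The other lists did not pass for elaidic acid against control. Their medians were 0.87 for sterol-regulated uptake and control, 0.26 for LXR and bile acid, 0.34 for NF-kB and cytokines, 0.12 for gluconeogenesis, 0.15 for glycolysis and hypoxia, 0.20 for p53 targets, -0.02 for TGF-beta, matrix and adhesion, -0.08 for xenobiotic metabolism, 0.53 for metallothionein and heat shock and 0.53 for common reference genes. Only 5 of the 9 members of the sterol-regulated list were tested. Its mean was 0.90 higher, with every elaidic acid sample above every control sample (exact permutation p = 0.0286). Within series A it was 0.41 higher (exact permutation p = 0.40). Probes of INSIG1 and SCD, left out of the test, lie near background, with mean intensities of 4.66 and 14.4. Their changes with an offset of 50, which presses values at that level towards 0, were 0.02 and 0.07 (0.09 and -0.14 with the slide series block), and they say little about these genes.

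Mitotic transcripts outside the fixed lists may be broadly higher with elaidic acid. A list of 36 such genes, written after the values were seen, had 25 tested members with a median of 0.83 within series A, 22 of them higher (camera p = 1.8e-13, and p = 6.0e-04 with an estimated correlation). Over all samples the median was 1.09, and NUSAP1, CDCA5 and FAM83D, all genes of the mitotic apparatus or of sister chromatid cohesion, passed. In oleic acid against control its median was 0.28 with 21 of 25 higher (p = 0.021 with an estimated correlation), and none passed limma by itself. In stearic acid against control its median was 0.70 with 21 of 25 higher (p = 0.036 with an estimated correlation), or 0.24 with slide series as a block (p = 0.25 with an estimated correlation). As the list was chosen after the result, it tests the pattern only in part.

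The samples of each comparison were split in all 35 ways into groups of 4. For elaidic acid against control 2 splits gave as many probes as the real 74, so that chance could not be excluded. The other gave 3205 and parted control replicates 1 and 3 and elaidic acid replicates 2 and 4, all of series A, from control replicates 2 and 4 of series A and elaidic acid replicates 1 and 3 of series B. The first 4 lay between -125 and -44.5 on the first principal component and the others between -16.02 and 96.3, which points to a structure of the samples along that component. With slide series as a block limma called 9 probes. For oleic acid against control the real count was 0, so that all 35 splits gave as many by construction (highest other 1), and the splits say nothing about chance there. In the other comparisons only the real split, 1 of 35, gave as many in the model without slide series. The counts were 6825 probes for stearic acid against control (highest other 0) and 73 for elaidic against oleic acid (highest other 4). They were 91 for elaidic against stearic acid (highest other 0) and 9057 for oleic against stearic acid (highest other 1). A share of 1 in 35 is the smallest possible and was not adjusted over the comparisons, so that chance is not excluded. For stearic acid against control and oleic against stearic acid the real split is also the split by slide series. Every other split there mixes both series on each side, which adds the series difference to the spread, so that low counts say little about chance. In the comparisons of elaidic with oleic and with stearic acid it places 2 arrays of the other series on 1 side, and with slide series as a block the counts were 5 and 1, so that slide series is not excluded by the splits in any of these 4. With only the 2 groups in the model limma called 0 in either, and for elaidic against stearic acid it called 0 without any 1 of elaidic acid replicates 2, 3 and 4 or stearic acid replicates 1, 2, 3 and 4, and 49 without elaidic acid replicate 1, so that these counts stay uncertain.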
